A study of Mus musculus with 6 samples.

How the data were processed

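RNA was sequenced from 6 samples of B16F10 mouse melanoma cells, 3 treated with DMSO and 3 with GSK126 at 10 µM. Per the labels' protocols, RNA was isolated with a column kit and libraries followed standard Illumina protocols. Per the submitters' processing notes, reads were base-called with CASAVA 1.8 and aligned with HISAT2 to GRCm38.p4/mm10. The counting tool, its version, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart. The duration of the treatment is not given in the sources used here either.

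The authors deposited raw read counts per gene for each sample, whole numbers for 54838 genes with Ensembl identifiers, symbols and GRCm38 positions per the file headers. They also deposited FPKM values of the same libraries in a single table. The FPKM values deposited by the authors were proportional to the counts within each gene, divided by the library's summed gene count, to within a ratio of 1.000048 between libraries over 12864 genes. They are therefore the same measurement on another scale, and the counts were used for all main results. Of the gene identifiers, 54809 are also in GENCODE M21, and 54123 of those have the same start and end there, so the GRCm38 positions printed are those of the files. A symbol carried by several identifiers was kept for the identifier with the most reads, and 103 other identifiers kept their number behind the symbol.

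Samples were grouped by their treatment label. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM normalisation and the quasi-likelihood F test (glmQLFit, glmQLFTest) with the group as the only term. This left 13601 genes, which held over 99% of the counts of each library (99.8674% at the least). P-values were adjusted by the Benjamini-Hochberg method over those genes, with a threshold of 0.05, and a second count took genes with an absolute log2 fold change of at least 1. The standard error of a log2 fold change was derived from its F statistic. CPM values use the TMM-scaled library sizes, and the TMM factors ranged from 0.994 to 1.007. The biological coefficient of variation was 0.119, and the median standard error of the log2 fold change was 0.0872 for the 10973 genes with at least 5 CPM on average. The library totals ran from 13594939 to 14713373 counts.

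The gene lists, the rule for naming genes, the main test and the alternatives other than the one that leaves out genes sharing exons were fixed before the data were examined. There were 27 lists, covering PRC2 subunits, Polycomb-repressed developmental regulators, 8 lists of lipid metabolism and their union, arachidonate and phospholipid remodelling, lysosome, pigmentation, cell cycle, CDK inhibitors and p53 targets, MHC class I, interferon-stimulated genes, the unfolded protein and integrated stress responses, oxidative stress, mesenchymal genes, glycolysis, mitochondrially encoded genes, housekeeping genes and markers of 4 other cell types. Each was tested with camera from the edgeR and limma (3.58.1) packages with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved relative to the other genes.

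The rule for naming genes took Ezh2, Ezh1, Eed and Suz12 whatever their result. It took the 6 genes with the largest positive and the 6 with the largest negative log2 fold change, and the 6 with the smallest p in each direction, among changed genes with at least 5 CPM on average and groups that did not overlap. Predicted genes, clone names and pseudogenes were left out of those. From each list it took up to 4 changed members with the largest absolute change, or else the most abundant member. This gave 89 genes, of which 1 is not reported here. Slc2a3, named beside its list, was chosen after its value was seen, as were the partners of overlapping genes. A gene was called overlapping where GENCODE M21 gives it exons in common with another gene that had at least 10% as many reads. That was the case for 2353 tested genes and 205 of the changed ones.

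Replicates were compared before they were averaged. A chi-square statistic over genes exceeded its degrees of freedom by a factor of 7.60 to 14.3 in the 6 pairs of replicates within a group. The statistic of the median gene was 2.24 to 4.31 times the median expected from counting noise alone. The spread between replicates was therefore above counting noise in each pair.

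The test was tested on simulated counts with the means, library sizes and dispersions of these samples and 200 changed genes. With 13464 genes tested, edgeR recovered 56 of 100 genes changed 1.5-fold and 99 of 100 changed 2-fold, while 10 unchanged genes were called. DESeq2, run on 13601 genes, recovered 69 and 99 and called 34 unchanged genes, and limma-voom, run on 13464, recovered 56 and 97 and called 11. In a separate simulation with 13457 genes tested, among 20 unchanged lists 0 were called, and a list of 20 genes raised 1.3-fold was called. Genes were simulated independently of each other. That simulation therefore cannot show how often camera calls unchanged lists whose genes are correlated.

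The alternatives were median-of-ratios size factors or library totals alone, DESeq2 (1.42.0) and limma-voom, no low-count filter or at least 1 CPM in at least 3 samples, a block for the replicate number, each sample left out in turn, limma-trend on log2(FPKM + 0.1) or log2(FPKM + 1) with a mean FPKM of at least 0.5 or without that filter, and removal of a smooth trend on gene length. Gene lengths were the union of exons in GENCODE M21, known for 13597 of the tested genes. For the lists, camera with an estimated correlation, fry, and lists without the member with the largest change were tried. A gene without an adjusted p from DESeq2 was left out of that comparison. The counts were also made with an adjusted p below 0.01 and with glmTreat against a 1.5-fold change. All deposited columns of per-sample values were used.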

Results

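Gene expression was measured by RNA sequencing in B16F10 cells, a pigmented mouse melanoma line, after culture with the vehicle DMSO or with 10 µM GSK126. GSK126 is an inhibitor of EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places the repressive methyl marks on lysine 27 of histone H3. The 6 libraries form 2 groups, with 3 DMSO samples and 3 GSK126 samples. The counts summed over genes were 13594939, 14072673 and 13597959 for DMSO replicates 1 to 3 and 14250457, 14713373 and 14410812 for GSK126 replicates 1 to 3. Between 18889 and 19267 genes had at least 1 read in a library. The series title names lipid metabolism and the response of these cells to EZH2 inhibition as its subject, and the single comparison is GSK126 against DMSO. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

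GSK126 changed 1503 of 13601 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), with 798 higher and 705 lower. Of these, 138 differed at least 2-fold, 88 of them higher and 50 lower. By the rule for naming genes, which asks for at least 5 CPM on average over all samples, Mgll had the largest rise. Mgll, the lipase that splits monoacylglycerols, rose 6.92-fold, from 2.96 ± 1.48 to 20.4 ± 9.70 CPM (the edgeR counts scaled for library size, mean ± SD, n = 3). Its log2 fold change ran from 1.33 to 3.20 over the alternatives, while that of Shc4 was never below 2.04, so the rank of Mgll depended on the setting. Shc4, an adaptor of receptor tyrosine kinases, rose 5.58-fold, and the immediate early transcription factor gene Egr1 rose 4.83-fold. Bnip3, a mitophagy receptor, rose 4.14-fold from 21.2 ± 0.947 to 87.9 ± 6.67 CPM (SD, n = 3).

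Slc16a3, which encodes the lactate exporter MCT4, rose 3.65-fold, and Ablim1, an actin-binding protein gene, rose 3.64-fold. The genes with the smallest p among those that rose also included Pfkl, the liver-type phosphofructokinase (1.84-fold), Pdk1, a kinase that inhibits pyruvate dehydrogenase (2.46-fold), and Smpd1, the lysosomal acid sphingomyelinase (1.77-fold). Among genes that fell, Slc7a11, the cystine importer, went from 68.0 ± 3.08 to 20.7 ± 0.950 CPM (SD, n = 3; log2 fold change -1.72, SE 0.07, adjusted p = 0.000155 by edgeR). Etv5, an ETS transcription factor gene, had a log2 fold change of -1.75 (SE 0.13), the adhesion molecule gene Mcam one of -1.57 (SE 0.07), Ttpal one of -1.64 (SE 0.22) and the adenylate kinase gene Ak4 one of -1.50 (SE 0.19). Cyclin D1 (Ccnd1, -1.11), Gsdmc of the gasdermin family (-0.95) and calponin 2 (Cnn2, -1.04) completed the genes with the smallest p among those that fell. The largest fall among genes with at least 5 CPM on average was assigned to Ube2v1 (log2 fold change -2.65, SE 0.14). It is uncertain, because Ube2v1 (GRCm38 chromosome 2, 167607638 to 167632095) shares 1673 bp of exons with Gm20431, whose counts rose (log2 fold change 1.18, SE 0.19), and the summed counts of both genes did not pass the test (0.12, SE 0.10, adjusted p = 0.467 by edgeR). Shc4 shares 527 bp of exons with Eid1, for which the log2 fold change was 0.04 (SE 0.05). By a match of gene descriptions, Etv5 and Gsdmc have 1 and 2 annotated pseudogenes that could take part of their reads.

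The samples of both groups did not overlap in 34.4% of all tested genes, against 10% expected by chance for 3 against 3. Smaller sets of libraries gave fewer calls. The count was 529 without DMSO replicate 1, 577 without DMSO replicate 2, 694 without DMSO replicate 3, 698 without GSK126 replicate 1, 815 without GSK126 replicate 2 and 1243 without GSK126 replicate 3. The call for Mgll ended without DMSO replicate 1 (log2 fold change 2.79, adjusted p = 0.0581 by edgeR). GSK126 replicate 3 stood apart from the other members of its group on the second principal component (18.8% of the variance). In this library, 74 ribosomal protein genes had a median deviation of -0.23 on the log2 scale from the mean of the other GSK126 samples.

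**Figure D1:**
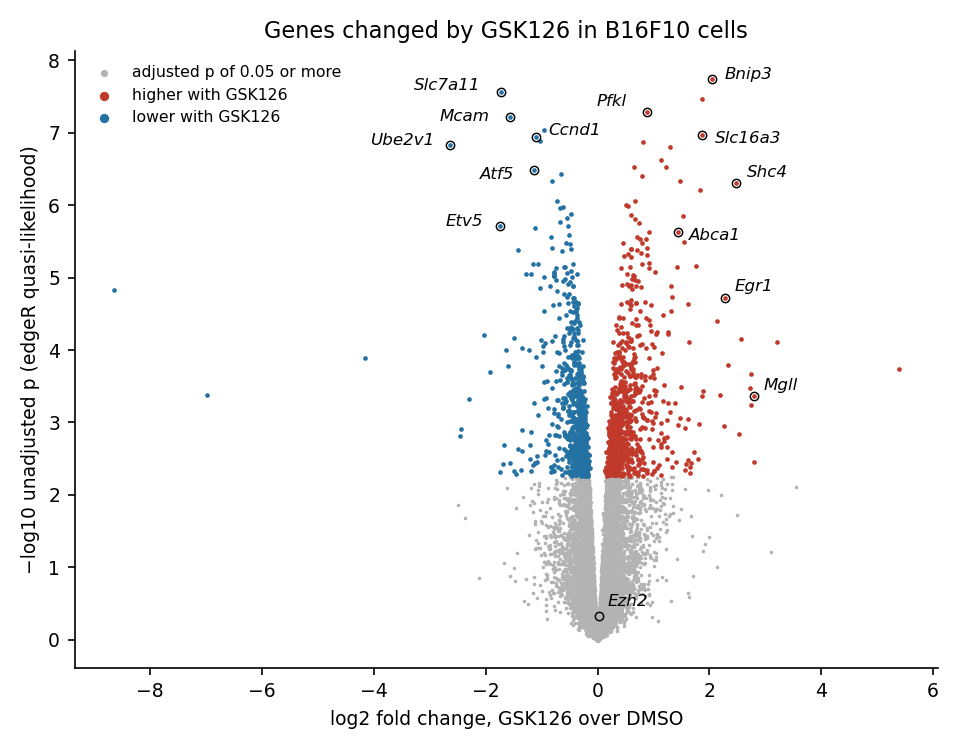
Log2 fold change between GSK126 and DMSO (x axis) against the -log10 of the unadjusted p of the edgeR quasi-likelihood test (y axis) for the 13601 genes tested, each point a gene. Red points are the 798 genes that were higher and blue points the 705 that were lower at an adjusted p below 0.05, and circles mark genes named in the text.

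The target of the inhibitor was expressed at the same level in both groups. Ezh2 (GRCm38 chromosome 6, 47530139 to 47595341) stood at 189 ± 4.84 CPM with DMSO and 193 ± 3.47 CPM with GSK126 (SD, n = 3; log2 fold change 0.03, SE 0.04, adjusted p = 0.669 by edgeR). For the other core subunits the log2 fold changes were 0.19 (SE 0.06) for Ezh1, -0.21 (SE 0.06) for Eed and -0.30 (SE 0.22) for Suz12, none past the test. Suz12 had 1884 reads in GSK126 replicate 3 and between 3314 and 3698 in the other 5 libraries. Of the 12 PRC2 subunits and partners, Jarid2 rose (log2 fold change 0.37, SE 0.06) and Aebp2 fell (-0.25, SE 0.05), while 2 rose and 3 fell when adjusted over the list alone. The list did not move relative to other genes (camera adjusted p = 0.609). The calls of Jarid2 and Aebp2 each ended with 4 of the 6 libraries left out singly, at adjusted p values of up to 0.0623 and 0.0898 by edgeR.

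Most developmental regulators that are classical Polycomb targets stayed at low or undetected levels, although Hoxd13, Foxc1 and Tbx15 averaged 33.0, 16.2 and 13.9 CPM. Of the 52 genes in that list, 30 had 0 reads in every library, 8 had too few reads to test and 14 were tested. Only Hoxb13 among them rose, with 6, 4 and 9 reads in the DMSO samples and 16, 30 and 18 in the GSK126 samples (log2 fold change 1.65, SE 0.40, adjusted p = 0.0422 by edgeR). That call ended when any 1 of the 6 libraries was left out (adjusted p from 0.0663 to 0.131). Adjusted over the list alone, 1 rose and 1 fell. The reads over all 52 genes, not scaled for library size, summed to 5009 in the DMSO samples and 5014 in the GSK126 samples. Expressed members carry these sums, with Hoxd13 alone at 439 to 494 reads in each library. The median log2 fold change of the 14 tested genes was -0.09 (camera adjusted p = 0.609).

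Genes of cholesterol biosynthesis rose together with GSK126. Of the 21 enzymes of the pathway, 17 rose, 0 fell and 4 did not pass the test, and 19 rose when adjusted over the list alone. The median log2 fold change was 0.64 (camera adjusted p = 4.08e-23, and adjusted p = 0.0285 with an estimated correlation). Mvd, the mevalonate diphosphate decarboxylase, went from 17.7 ± 3.50 to 34.0 ± 2.34 CPM, and Nsdhl, a sterol dehydrogenase, from 28.7 ± 2.47 to 53.9 ± 2.30 CPM (SD, n = 3). Their log2 fold changes were 0.94 (SE 0.14) and 0.91 (SE 0.08). Pmvk, the phosphomevalonate kinase, had a log2 fold change of 0.93 (SE 0.19). Tm7sf2, a sterol reductase gene, had the largest change in the list (1.34, SE 0.30), but it shares 532 bp of exons with Vps51, whose log2 fold change was -0.55 (SE 0.43), and the summed counts of both did not pass the test (0.27, SE 0.08, adjusted p = 0.0723 by edgeR). The calls of Tm7sf2 and Pmvk ended with 5 and 3 of the 6 libraries left out singly, at adjusted p values of up to 0.105 and 0.0943 by edgeR.

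Genes that control sterol uptake and the SREBP transcription factors followed the same direction. Of 12 measured, 7 rose, 0 fell and 5 did not pass, and 8 rose when adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 8.24e-05, and adjusted p = 0.0576 with an estimated correlation). The transcript of Srebf2, the main activator of sterol synthesis genes, rose from 226 ± 5.96 to 307 ± 9.05 CPM (SD, n = 3; log2 fold change 0.44, SE 0.04). Stard4, a carrier of cholesterol within the cell, rose by 0.59 (SE 0.10), the lysosomal cholesterol exporter Npc1 by 0.30 (SE 0.05) and the sterol sensor gene Insig1 by 0.29 (SE 0.05), all on the log2 scale. The Insig1 call ended without DMSO replicate 1 (adjusted p = 0.0558 by edgeR). Among 6 measured targets of the oxysterol receptor LXR and genes of cholesterol efflux, 3 rose and 0 fell, and 4 rose when adjusted over the list alone (median log2 fold change 0.54, camera adjusted p = 1.87e-05, and adjusted p = 0.0576 with an estimated correlation). Abca1, the cholesterol exporter, went from 20.4 ± 2.70 to 55.6 ± 3.89 CPM (2.73-fold, SD, n = 3). Mylip, which targets the LDL receptor for degradation, rose by 0.58 (SE 0.12) and the phospholipid-remodelling enzyme gene Lpcat3 by 0.49 (SE 0.06) on the log2 scale. Npc1 and Lpcat3 share 511 and 334 bp of exons with Rmc1 and Emg1, so part of their reads is uncertain. The Mylip call ended with 4 of the 6 libraries left out singly (adjusted p of up to 0.0847 by edgeR).

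Genes of fatty acid synthesis, elongation and desaturation were higher in part. Of 20 measured, 8 rose, 0 fell and 12 did not pass, and 12 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 1.66e-08, and adjusted p = 0.0608 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, went from 82.6 ± 6.56 to 143 ± 6.52 CPM (SD, n = 3; log2 fold change 0.80, SE 0.07). Acss2, which makes acetyl-CoA from acetate, rose by 0.67 (SE 0.09), the desaturase gene Fads2 by 0.62 (SE 0.07) and malic enzyme 1 (Me1) by 0.60 (SE 0.06) on the log2 scale. Of 12 measured genes of fatty acid uptake and activation, Acsl3 (log2 fold change 0.35, SE 0.04) and Lrp1 (0.34, SE 0.06) rose and 0 fell, and 5 rose and 1 fell when adjusted over the list alone. Acss2 and Acsl3 share 197 and 244 bp of exons with Ggt7 and Utp14b, so part of their reads is uncertain. The uptake list passed the test (camera adjusted p = 0.0116) but not with an estimated correlation (adjusted p = 0.117), and the Lrp1 call ended with 3 of the 6 libraries left out singly (adjusted p of up to 0.0593 by edgeR).

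The other lipid lists did not move relative to other genes by camera, while fry, which tests a list against no change, called those of triglycerides (adjusted p = 0.0139) and sphingolipids (adjusted p = 0.0241) higher. Among 18 genes of triglyceride synthesis and lipid droplets, Mgll rose and G0s2, an inhibitor of triglyceride lipase, fell (log2 fold change -1.12, SE 0.27), with 3 up and 1 down when adjusted over the list alone (camera adjusted p = 0.211). The G0s2 call ended when any 1 of the 6 libraries was left out (adjusted p from 0.0524 to 0.115 by edgeR). Among 25 fatty acid oxidation genes, only the coactivator gene Ppargc1a rose (log2 fold change 0.47, SE 0.08), also when adjusted over the list alone (camera adjusted p = 0.167), and its call ended without DMSO replicate 2 (adjusted p = 0.0520 by edgeR). The oxidation list passed without GSK126 replicate 3 (camera adjusted p = 0.0299) and with unfiltered FPKM (adjusted p = 0.0494). Among 18 sphingolipid genes, 3 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0738, and 0.0430 without genes that share exons). Smpd1 went from 98.0 ± 1.05 to 173 ± 3.27 CPM (SD, n = 3). The sphingosine phosphate lyase gene Sgpl1 (log2 fold change 0.27, SE 0.05) and the ceramide synthase gene Cers6 (0.25, SE 0.06) also rose, while the ceramide synthase gene Cers2, which shares 75 bp of exons with Setdb1, fell (-0.21, SE 0.05). Those calls ended with 3, 6 and 5 of the 6 libraries left out singly, at adjusted p values of up to 0.0683, 0.152 and 0.0998. Of 8 arachidonate and phospholipid remodelling genes, Ptgds, a prostaglandin synthase gene, rose (log2 fold change 0.68, SE 0.12), and 2 rose when adjusted over the list alone (camera adjusted p = 0.161). The Ptgds call ended without DMSO replicate 1 or 2 (adjusted p of up to 0.0680 by edgeR), and without DMSO replicate 3 its list passed (camera adjusted p = 0.0318). The union of 8 lipid lists, without that of arachidonate, held 132 measured genes, of which 42 rose, 2 fell and 88 did not pass. With adjustment over the list alone, 57 rose and 3 fell (median log2 fold change 0.19, camera p = 1.64e-16, and p = 0.00136 with an estimated correlation).

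**Figure D2:**
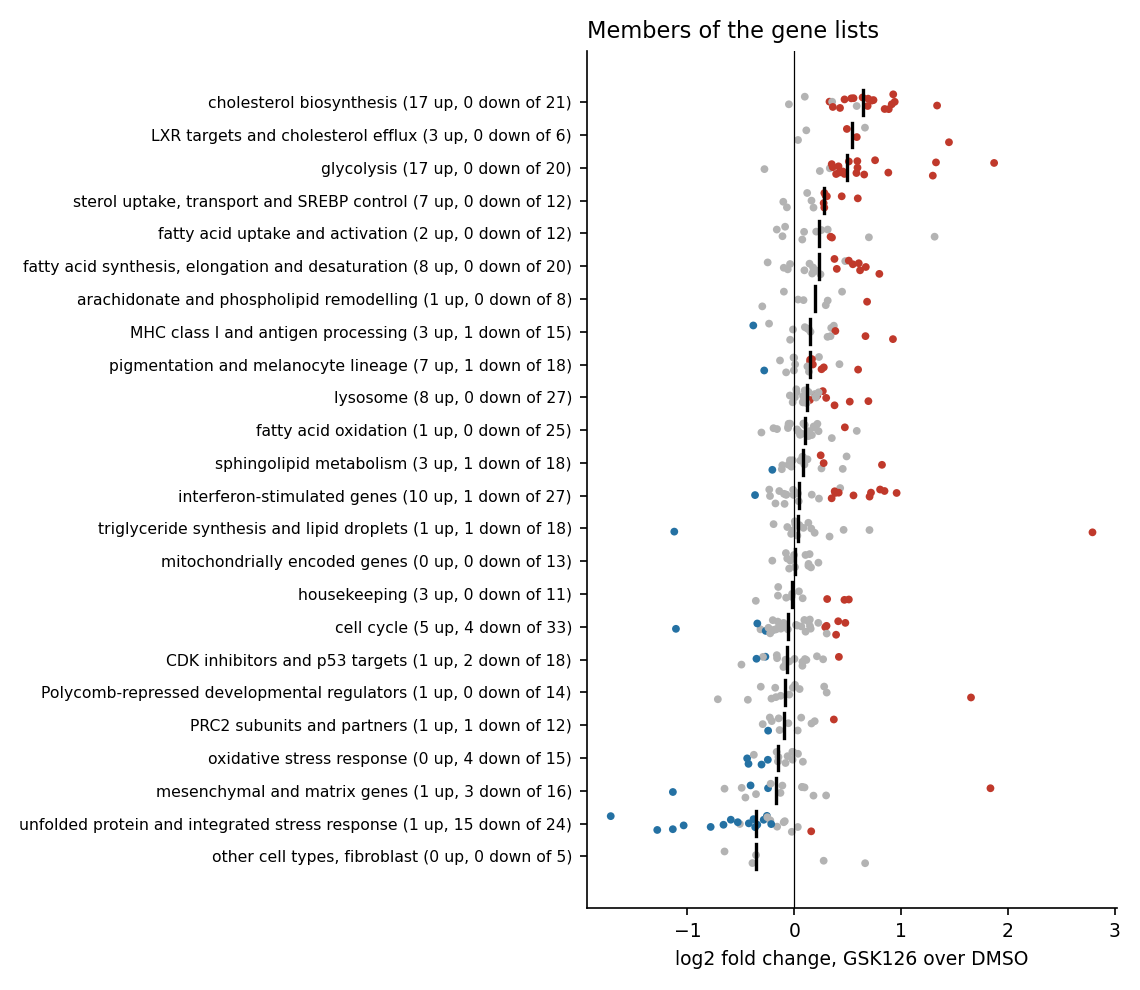
Log2 fold change between GSK126 and DMSO (x axis) of the measured members of each list with at least 3 of them (y axis), with red points for genes that rose, blue for genes that fell, grey for genes that did not pass the test and a black bar at the list's median. The medians run from 0.64 for cholesterol biosynthesis to -0.36 for the stress response list and the fibroblast markers.

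Glycolysis genes rose nearly throughout the pathway. Of 20 measured, 17 rose, 0 fell and 3 did not pass, and 18 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.49 (camera adjusted p = 1.63e-35, and adjusted p = 0.0285 with an estimated correlation). Slc16a3 went from 23.3 ± 2.59 to 85.0 ± 4.39 CPM, Pdk1 from 37.2 ± 2.54 to 91.4 ± 2.69 CPM, Pfkl from 186 ± 4.64 to 342 ± 3.31 CPM and the aldolase gene Aldoc from 8.76 ± 1.28 to 22.0 ± 2.32 CPM (SD, n = 3). The log2 fold changes were 1.87 (SE 0.09) for Slc16a3, 0.88 (SE 0.04) for Pfkl and 1.33 (SE 0.14) for Aldoc, and Pdk1 rose 2.46-fold. The glucose transporter gene Slc2a3 went the other way without passing the test over all genes (log2 fold change -0.28, SE 0.10, adjusted p = 0.108 by edgeR). None of the 13 mitochondrially encoded genes passed the edgeR test, also when adjusted over the list alone, and mt-Co1, the most abundant, had a log2 fold change of 0.10 (SE 0.05; camera adjusted p of the list 0.609). Of 11 housekeeping genes, 3 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.211, but fry adjusted p = 0.0139). Among them were the glycolytic genes Gapdh (log2 fold change 0.51, SE 0.07) and Pgk1 (0.47, SE 0.04). By a match of gene descriptions, Gapdh and Pgk1 have 3 and 2 annotated pseudogenes that could take part of their reads. Pseudogenes described in other words were not counted.

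Most genes of a joint list of the unfolded protein and integrated stress responses fell. The responses were not tested apart, so a fall of each of them is not shown. Of 24 measured, 15 fell, 1 rose and 8 did not pass, and 18 fell and 1 rose when adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 2.52e-22, and adjusted p = 0.0576 with an estimated correlation). Besides Slc7a11, the pseudokinase gene Trib3 fell (log2 fold change -1.28, SE 0.12), the transcription factor gene Atf5 went from 151 ± 6.19 to 68.6 ± 4.88 CPM and the glutathione-degrading enzyme gene Chac1 from 30.1 ± 2.28 to 14.7 ± 1.46 CPM (SD, n = 3). The log2 fold changes of Atf5 and Chac1 were -1.14 (SE 0.07) and -1.04 (SE 0.10). Atf5 shares 82 bp of exons with Nup62, so part of its reads is uncertain. Oxidative stress genes moved in the same direction, with 4 of 15 falling, 0 rising and the same counts when adjusted over the list alone (camera adjusted p = 0.0104, but adjusted p = 0.117 with an estimated correlation). The redox enzyme genes Txnrd1 (log2 fold change -0.44, SE 0.04) and Srxn1 (-0.43, SE 0.06) fell, as did Gclc of glutathione synthesis (-0.31, SE 0.06) and the glutathione reductase gene Gsr (-0.25, SE 0.06). The calls of Gclc and Gsr each ended with 5 of the 6 libraries left out singly (adjusted p of up to 0.0872 and 0.131 by edgeR), and without Txnrd1 the list no longer passed (camera adjusted p = 0.0539).

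**Figure D3:**
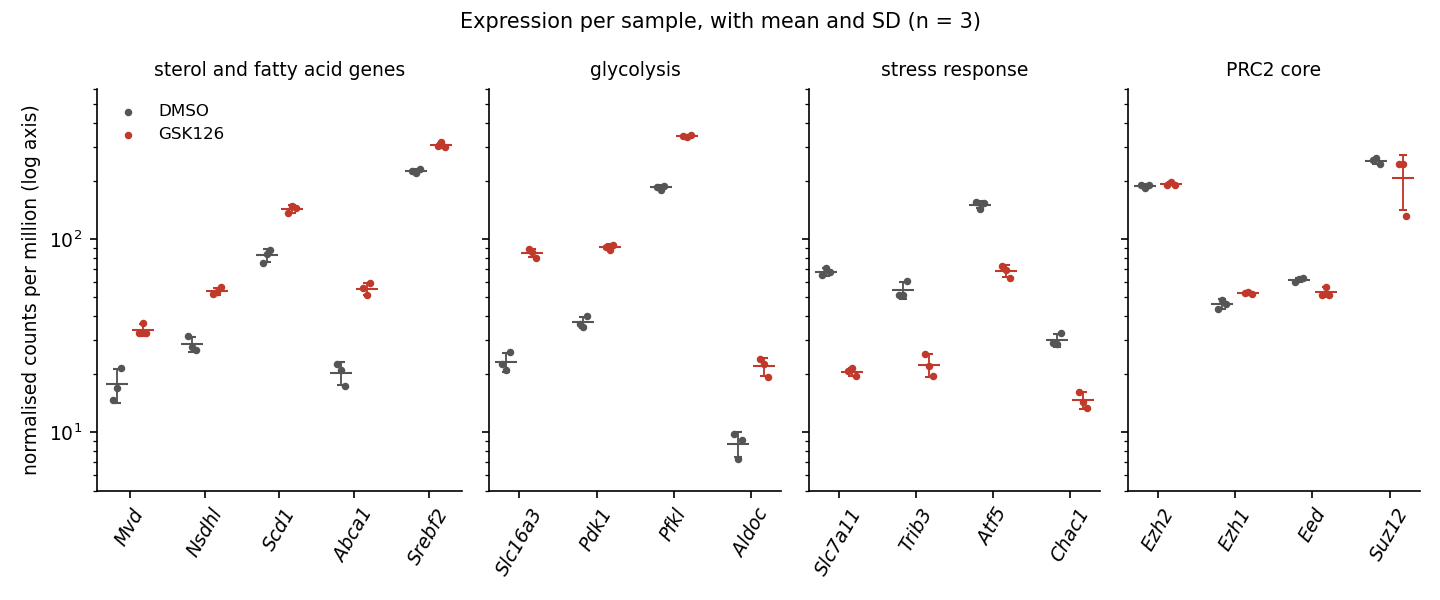
Normalised CPM (y axis, log scale) of selected genes in each sample, with grey points for DMSO and red for GSK126, a horizontal bar at the mean and error bars of 1 SD (n = 3). The samples of both groups are separate for each sterol, glycolysis and stress response gene shown, as they are for all 1503 changed genes. They are also separate for Ezh1 and Eed, which did not pass the test, and overlap for Ezh2 and Suz12.

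Part of the lysosomal and pigment cell genes rose, by smaller amounts. Of 27 lysosome genes, 8 rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 6.28e-05, but adjusted p = 0.117 with an estimated correlation). The log2 fold change was 0.69 (SE 0.07) for the sialidase gene Neu1, 0.52 (SE 0.06) for Naglu, 0.38 (SE 0.09) for Gla, both lysosomal glycosidases, and 0.30 (SE 0.06) for the proton pump subunit gene Atp6v1a. The calls of Gla and Atp6v1a ended with 6 and 3 of the 6 libraries left out singly (adjusted p of up to 0.114 and 0.0751 by edgeR). Of 18 pigmentation and melanocyte lineage genes, 7 rose and 1 fell, and 10 rose and 2 fell when adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.0116, but adjusted p = 0.345 with an estimated correlation). Mitf, the master regulator of the lineage, went from 650 ± 33.1 to 983 ± 30.5 CPM (SD, n = 3; log2 fold change 0.60, SE 0.05). The melanosome gene Pmel (log2 fold change 0.28, SE 0.03) and the receptor gene Met (0.25, SE 0.05) rose, while the melanosome antigen gene Mlana fell (-0.28, SE 0.06). The calls of Met and Mlana each ended with 3 of the 6 libraries left out singly (adjusted p of up to 0.0720 and 0.0934 by edgeR). With unfiltered FPKM the calls of Pmel, Met and Mlana ended (adjusted p = 0.212, 0.0576 and 0.214 by limma-trend), that of Mlana also with filtered FPKM (up to 0.0704), and without Mitf the list no longer passed (camera adjusted p = 0.0922).

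Cell cycle genes moved both ways, with 5 of 33 higher and 4 lower (8 and 10 when adjusted over the list alone; camera adjusted p = 0.609). Ccnd1, which drives entry into the cycle, went from 213 ± 1.38 to 98.8 ± 6.36 CPM (SD, n = 3). The proliferation marker Mki67 rose by 0.39 (SE 0.05) and the kinetochore genes Cenpf and Cenpe by 0.48 (SE 0.07) and 0.41 (SE 0.05) on the log2 scale. Of 18 CDK inhibitors and p53 targets, Trp53inp1 rose (log2 fold change 0.42, SE 0.07) and Sesn2 (-0.35, SE 0.06) and Mdm2 (-0.27, SE 0.05) fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.609). The Mdm2 call ended without DMSO replicate 1 or 2 (adjusted p of up to 0.0623 by edgeR). Of 16 mesenchymal and matrix genes, 1 rose and 3 fell, and 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.481). Osteopontin (Spp1) went from 6.91 ± 0.920 to 24.7 ± 1.35 CPM (SD, n = 3; log2 fold change 1.84, SE 0.12). The matricellular genes Ctgf (-1.14, SE 0.20) and Sparc (-0.41, SE 0.06) and the N-cadherin gene Cdh2 (-0.25, SE 0.05) fell. The Ctgf call ended without GSK126 replicate 1 (adjusted p = 0.0513 by edgeR), and the Cdh2 call with 5 of the 6 libraries left out singly (adjusted p of up to 0.106). That list passed the test in the downward direction without Spp1 (camera adjusted p = 0.0435) and with no low-count filter (adjusted p = 0.0444).

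Some genes of the antigen presentation and interferon lists rose, and most did not pass the test. Of 15 genes of MHC class I and antigen processing, 3 rose, 1 fell and 11 did not pass. When adjusted over the list alone, 5 rose and 1 fell (median log2 fold change 0.15, camera adjusted p = 0.0116, but adjusted p = 0.117 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, went from 25.6 ± 1.09 to 48.6 ± 3.75 CPM (SD, n = 3; log2 fold change 0.92, SE 0.08). Nlrc5, the transactivator of MHC class I genes, rose by 0.67 (SE 0.10) and the peptide transporter gene Tap2 by 0.38 (SE 0.10), while the log2 fold change of the peptidase gene Erap1, which shares 834 bp of exons with Cast, was -0.38 (SE 0.08). The calls of Tap2 and Erap1 ended with 6 and 5 of the 6 libraries left out singly (adjusted p of up to 0.147 and 0.0839 by edgeR), and without Cd274 the list no longer passed (camera adjusted p = 0.0931). Of 27 interferon-stimulated genes, 10 rose, 1 fell and 16 did not pass, and 11 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.04 (camera adjusted p = 0.000423, but adjusted p = 0.345 with an estimated correlation). The antiviral genes Mx1 (log2 fold change 0.96, SE 0.10), Oasl1 (0.80, SE 0.18) and Rsad2 (0.72, SE 0.07) and the chemokine gene Ccl5 (0.84, SE 0.17) had the largest changes. The calls of Oasl1 and Ccl5 each ended with 5 of the 6 libraries left out singly (adjusted p of up to 0.111 and 0.0826 by edgeR).

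Most markers of other cell types did not reach the tested range. Only 2 of 14 leukocyte markers reached the tested range, of which 0 passed, also when adjusted over the list alone (camera adjusted p = 0.896), and the more abundant of them, Cd68, stood at 2.44 ± 0.783 and 3.18 ± 0.0857 CPM (SD, n = 3). The single endothelial marker tested was Vwf, which rose from 2.89 ± 0.0661 to 6.02 ± 0.701 CPM (SD, n = 3), also when adjusted over the list alone, but not with unfiltered FPKM (adjusted p = 0.0823 by limma-trend). As a list of 1 gene it passed the list test (camera adjusted p = 0.0116), but not with an estimated correlation (adjusted p = 0.117), no low-count filter (0.243) or unfiltered FPKM (0.450). No epithelial marker reached the tested range. Of 10 fibroblast markers 5 reached the tested range, of which 0 passed over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.703). Col1a2, at 19.5 CPM on average, had a log2 fold change of -0.36 (SE 0.11), and it passed without GSK126 replicate 1 (adjusted p = 0.0487 by edgeR). Over all 27 lists, 26 had a measured member, and 13 passed the camera test, 11 of them upwards and 2 downwards. With the correlation between genes estimated from these samples, the lists of cholesterol biosynthesis and glycolysis passed.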

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

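The alternative that leaves out genes sharing exons with another gene was chosen after the data were seen. The 1503 changed genes became 1486 to 1520 with other scalings or the CPM filter, 1435 with DESeq2, 1477 with limma-voom, 1302 and 1312 with filtered FPKM, 1711 with the length trend removed and 1349 without genes that share exons. Counts moved by more than 1.5 times in other settings. With no low-count filter 899 genes changed, with unfiltered FPKM 889 and at an adjusted p below 0.01 there were 398. The first 2 settings test more genes, which makes the adjustment heavier. Genes changed at least 2-fold went from 138 to 78 and 35 with filtered FPKM at pseudocounts of 0.1 and 1, whereas unfiltered FPKM at 0.1 gave 130. Both filtered settings tested the same 13400 genes and differed only in the pseudocount, which shrinks the log2 ratios of low values. The unfiltered setting differed from the filtered one at 0.1 only in the filter. Why filtered FPKM at 0.1 gave fewer such genes than the counts was not tested. With glmTreat against a 1.5-fold change, 37 passed. With single libraries left out, the counts ran from 529 to 1243, and from 85 (without DMSO replicate 1) to 126 for at least 2-fold, with fewer samples in each fit.

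The replicate numbers showed no clear pairing of the samples: the deviations of equally numbered samples correlated at 0.07, 0.02 and -0.04 across genes, and 3 of 6 samples correlated best with their own number. So few samples cannot exclude a weak pairing. With the replicate number as a block, 408 genes changed (230 higher, 178 lower), 74 of them at least 2-fold, and 13 lists passed.

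The 13 lists that passed became 2 with an estimated correlation, and numbered 11 to 16 in the other settings. The lipid lists together stayed higher under every alternative run, with p from 1.05e-16 to 0.00136. Of the 82 named genes called, 53 kept their call with each library left out in turn and 48 under every alternative run, and none changed sign. DESeq2 ended the calls of Cers6, Gla, Tap2 and Gsr, limma-voom that of Tm7sf2, and filtered FPKM those of Tm7sf2, Mlana and Oasl1. With no low-count filter 14 calls ended, and with unfiltered FPKM 19, Pmel and Vwf among them. The block for the replicate number ended 27 calls. Those of Npc1, Sesn2 and Trp53inp1, which no left-out library ended, were among them. Removing the length trend ended the calls of Cers6, G0s2 and Gsr (adjusted p values of 0.0781, 0.0590 and 0.0572), with log2 fold changes of 0.21, -1.03 and -0.23 against 0.25, -1.12 and -0.25. Totals of 13594939 to 14713373 counts per library limit what can be said of genes near 1 CPM, such as Hoxb13.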

Other observations

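All tests in this part were chosen after the data were seen, other than the comparison with other splits of the samples for changed genes, for those changed at least 2-fold, for the lists and for the lipid lists together. Chosen after as well were the 6 gene lists that come first, whose p-values from camera are therefore descriptive. GSK126 lowered genes that charge transfer RNAs in the cytosol. Of the 20 cytosolic aminoacyl-tRNA synthetase genes, 13 fell and 0 rose (median log2 fold change -0.31, camera adjusted p = 2.66e-13, and adjusted p = 0.0310 with an estimated correlation), among them Nars (-0.48, SE 0.04) and Lars (-0.48, SE 0.06). Of the 17 mitochondrial synthetase genes, Pars2 rose and 0 fell (median -0.09, camera adjusted p = 0.485). Targets of the hypoxia-inducible factors, glycolysis genes left out, rose in 17 of 27 cases and fell in 2 (median 0.45, camera adjusted p = 9.33e-20, and adjusted p = 0.00251 with an estimated correlation). Besides Bnip3, the peptide hormone gene Adm (1.26, SE 0.15), the lysyl oxidase gene Loxl2 (1.76, SE 0.16), the oxygen sensor gene Egln3 (0.96, SE 0.17) and the glycogen genes Pgm1 (0.79, SE 0.05) and Gys1 (0.59, SE 0.06) rose. Vegfa, a classical target, did not pass the test (-0.08, SE 0.09), and Ak4 and Car12 (-2.04, SE 0.25) fell.

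Feedback and output genes of ERK signalling fell in 11 of 16 cases and rose in 1 (median -0.58, camera adjusted p = 3.26e-15, and adjusted p = 0.00251 with an estimated correlation). Besides Etv5 and Ccnd1, they included Spry4 (-1.11, SE 0.15), Dusp6 (-0.62, SE 0.08), Dusp4 (-0.55, SE 0.06) and Myc (-0.67, SE 0.10). Immediate early genes, which ERK also induces, went the other way. Of 14 measured, 6 rose and 0 fell (median 0.81, camera adjusted p = 3.97e-10, and adjusted p = 0.0310 with an estimated correlation), with Fos at 1.61 (SE 0.17) and Junb at 0.87 (SE 0.10). In a list of mainly actin cytoskeleton genes controlled by serum response factor, 7 of 13 fell and 0 rose (median -0.47, camera adjusted p = 3.67e-14, and adjusted p = 0.00251 with an estimated correlation). Those that fell included Flna (-0.66, SE 0.04), Zyx (-0.78, SE 0.07) and Srf itself (-0.62, SE 0.06), besides Cnn2 and Ctgf, named above. Srf, Ctgf and Cyr61 are in this list but are not cytoskeleton genes. A trait that links these lists was not tested.

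An inhibitor of EZH2 would be thought to release silent genes, a hypothesis tested with genes that had 0 reads in all samples of either group. There were 57 genes with 0 reads in every DMSO sample and at least 1 in every GSK126 sample, and 58 of the opposite kind, so 49.6% were read only with GSK126 (exact binomial 95% interval 40.1 to 59.0%). Together these were 115 genes, and the splits that mix the groups gave 95 to 113, so the share rests on sampling of few reads and the hypothesis stays open. With at least 5 reads in each sample of the group with reads, the counts were 1 and 3. Among 555 tested genes with a mean under 1 CPM over all 6 samples, 16 rose and 8 fell.

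Ube2v1 had the largest fall among genes with at least 5 CPM while Gm20431, which overlaps it (GRCm38 chromosome 2, 167607850 to 167661496), rose. If Gm20431 had stayed level, the summed counts would have changed by -0.92 on the log2 scale, and they changed by 0.12 (SE 0.10). Reads assigned to either gene may account for the fall. Only this pair was summed, so reads of any other gene that overlaps Gm20431 were not weighed. A switch between the transcripts of both genes caused by GSK126 would give the same sums and was not tested, so it stays open.

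GSK126 replicate 3 deviated more from its group than any other library (0.178 against at most 0.141, as the scaled median absolute deviation of log2 CPM). Its deviations rose with gene length (Spearman's rho 0.39 across genes, which are not independent replicates), and log2 fold changes between the groups also did so weakly (rho 0.17). Removing the length trend left 82.5% of the excess deviation, which argues against length as the whole cause. What else sets this library apart stays open, and no biological explanation was tested, since its label is that of the other GSK126 samples.

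Some genes had counts at 2 levels within a group. Kctd12 had 938, 0 and 0 reads in the DMSO samples and 1026, 0 and 1063 in the GSK126 samples, Ets1 had 2612 in DMSO replicate 3 and 9003 to 9527 in the other 5 libraries, and Rac1 had 1937 to 2162 in 3 libraries from both groups and 5305 to 5532 in the others. Of 3540 genes with a mean of at least 1000 reads, 224 (6.33%) differed at least 1.5-fold between samples of a group. Of the 224 genes, 28 shared exons with another counted gene, against 397 of the other genes. The odds ratio was 1.05 (95% interval 0.671 to 1.59). For the set as a whole, these values argue against overlapping genes as the main source. The 1.5-fold rule does not ask for 2 levels. It also took genes such as Rps24, with 4234, 4172 and 3785 reads in the DMSO samples and 4233, 4280 and 2831 in the GSK126 samples. Genes with counts at 2 levels were not tested separately, so overlap as their source stays open. GSK126 replicate 3 was the outlying sample for 86 of the 224 genes (38.4%, 95% interval 32.0 to 45.1%). Each of the other libraries was so for 21 to 34 genes. These values argue against GSK126 replicate 3 as the source of most of the 224 genes, although it contributed more than any other library. The unnamed counting step may be a source, which cannot be examined without the reads, and no biological explanation was tested.

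With 10 splits of the 6 samples into groups of 3, no share below 0.05 is possible, so only the values are given. In the other splits each set mixes the treatments. An effect of GSK126 would then add to the spread within the sets and lower the number of changed genes. These splits are therefore no measure of what would occur without an effect. The real split gave 1503 changed genes and the highest of the other splits, which mix the groups, 4, and for changes of at least 2-fold the numbers were 138 and 4. For the lists the real split passed 13 and the highest other split 6. The lipid lists together had a p of 1.64e-16 in the real split, and the lowest p of the other splits was 2.11e-05. In each case 1 of the 10 splits, the real one, reached its value. Genes with at least 5 CPM whose samples lay at least 2-fold apart between the sets numbered 28 in the real split and 0 to 4 in the others.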
